A study of Solanum lycopersicum with 30 samples.

How the data were processed

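Tomato (Solanum lycopersicum) leaves were compared after challenge with sap carrying tobacco mosaic virus (TMV), a positive-strand RNA virus, and after a mock treatment with leaf sap. Per the labels, 3 genotypes were used: a susceptible line (n), a resistant line (N), and sun1-1, a mutant of the N genotype with enhanced susceptibility. N is a resistance gene from tobacco whose product is a receptor with TIR, nucleotide-binding and leucine-rich repeat domains. Plants had grown for 28 to 35 days at 25 °C with 16 h of light and 8 h of dark. Leaves were taken at 3, 9 or 27 h, and each RNA sample came from a single plant. For each sample 25 µg of total RNA was labelled, and each of the 30 arrays carried a Cy3-labelled TMV sample and a Cy5-labelled mock sample of the same genotype and time. There were 3 arrays for each susceptible and sun1-1 group and 4 for each resistant group, in 9 groups. For 2 resistant arrays, replicate 4 at 9 h and at 27 h, the protocol of the TMV channel named another time, 3 h and 9 h. They were grouped by their titles.

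The deposited values are log2 ratios of the 2 channels of an array, which the authors had centred on about 0. The submitters' processing notes name limma without a version. The scanner, the background correction, the normalization method and the filter behind the empty cells were not given in the sources used here. The log base was read from the values: 100% of the 5154 values at a decrease of 2-fold or more lay within 0.002 of the log2 of a ratio with 2 decimals. The array titles name mock before TMV, but the labels do not state which channel is the numerator, and no array had the dyes exchanged. Signs are therefore given as deposited, a positive value meaning more signal in the numerator channel, and neither reading was chosen from gene values. The name TMV against mock gives the samples compared and not the direction of the ratio. A positive value can thus mean more signal after TMV or after mock treatment. Any dye effect of a probe is part of the value of TMV against mock, while it cancels in a difference between genotypes or times.

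The array held 32448 spots. Of these, 1630 carried 1 gene symbol, 180 carried several, and 30638 carried none. The 905 annotated pairs of spots of 1 clone all followed a fixed layout, which gave 15360 clone pairs. Paired spots outside the annotated ones correlated at r = 0.769 across spots, so the spots of a pair were averaged. Of the clones, 12593 had a value on at least 1 array, 650 had one on all 30 arrays, and 815 carried a single symbol, 430 symbols in all. None of the 430 gene identifiers behind those symbols (0 matched) was in the tomato gene table, so symbols are used as the platform gives them and LOC symbols are left without a name. Whether the symbols belong to tomato genes was therefore not established, and functions given below are those of the symbol. The column of sun1-1 27 h replicate 2 was displaced: its mean absolute correlation with the other 29 arrays was 0.0115 as deposited and 0.172 after a move of 1 row, whereas the 29 other arrays were best without a move. It was moved for the values reported, a choice made after the data were seen.

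The comparisons were fixed before the data were examined, with R 4.3.3 and limma 3.58.1. A linear model with 1 mean for each of the 9 groups was fitted to each clone, with moderated tests by limma and 1 prior spread for all clones (prior degrees of freedom 5.60, prior SD 0.33 on the log2 scale). Each SE rests on 1 residual spread of the clone or gene, taken as equal in all 9 groups. Where the SD of a group is wide, its mean is therefore known less well than the SE gives. There were 21 comparisons: TMV against mock in each group, the 3 genotypes against each other at each time, and the change over the 3 times within a genotype by limma's moderated F test. A clone entered a comparison with at least 2 arrays in each group compared, which left 5004 to 8219 clones. P values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. The mean of the 3 genotypes at each time was added after the data were seen, as was a fit to genes, with the clones of a symbol averaged (426 genes). Clones were named by a fixed rule: those past the threshold with the largest values, and where fewer than 3 passed, the 3 symbols with the smallest p. The rule also named clones from 23 gene lists, matched on words in the symbols because no gene descriptions came with them, and only 2 lists, pathogenesis-related proteins and WRKY transcription factors, matched any clone (PR1B and STWRKY8). No list had the 5 clones needed for a test, so no list was tested and the alternatives for list tests could not be run. A further 33 genes with a well known function were examined after the data were seen.

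The alternatives were centring each array on its median, scaling the arrays to 1 spread, clones with a value on all 30 arrays, array quality weights, the replicate number as a block, each replicate left out in turn, a fit to the arrays of the compared groups, and the 2 arrays of conflicting time left out. Added after the data were seen were the displaced column as deposited, that array left out, the array of the widest spread left out, clones averaged by gene, which also leaves out clones without a symbol, and the 815 clones with a single symbol tested alone. The model was tested on simulated data with 200 changed clones in each comparison. It recovered 68% of the clones changed by 1 log2 unit and 99% of those changed by 2 in the resistant 27 h comparison, and 30% and 87% between resistant and susceptible at 27 h. The share of false calls over the 5 simulated comparisons was 1 to 6.18%. Simulated clones were independent of each other, which those on the arrays were not. For arrays the number of replicates limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.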

Results

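Leaf RNA from TMV-challenged and mock-treated tomato plants was compared on 30 2-colour arrays, in susceptible, resistant and sun1-1 plants at 3, 9 and 27 h, with 3 arrays for each susceptible and sun1-1 group and 4 for each resistant group. An array gave values for 2173 to 9511 clones (median 6979.5), and 65.0% of all cells were empty. The SD of the log2 ratios on an array ranged from 0.22 to 1.35. The widest spread was that of sun1-1 3 h replicate 3, where 40.1% of 2635 clones differed 2-fold or more between the channels, against a median of 1.57% over the arrays. Sun1-1 27 h replicate 1 also stood apart from its group, with 12.5% against 1.17% and 1.08% for replicates 2 and 3. Duplicate spots of a clone correlated at r = 0.243 to 0.917 across clones, with a median of 0.747 and the lowest value on susceptible 9 h replicate 2.

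Arrays of the same genotype and time correlated weakly. Over the 435 pairs of arrays the correlation across clones ran from -0.571 to 0.554, with 45 pairs above 0.3 and 20 below -0.3. Of the 36 pairs within a group, 14 were below 0, among them the 3 pairs of sun1-1 at 9 h. Pairs sharing genotype and time had a mean r of 0.0809 and other pairs 0.0388 (two-sided permutation p = 0.199, Benjamini-Hochberg adjusted p = 0.332 over 5 label tests). Clones are not independent replicates in these correlations.

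**Figure D1:**
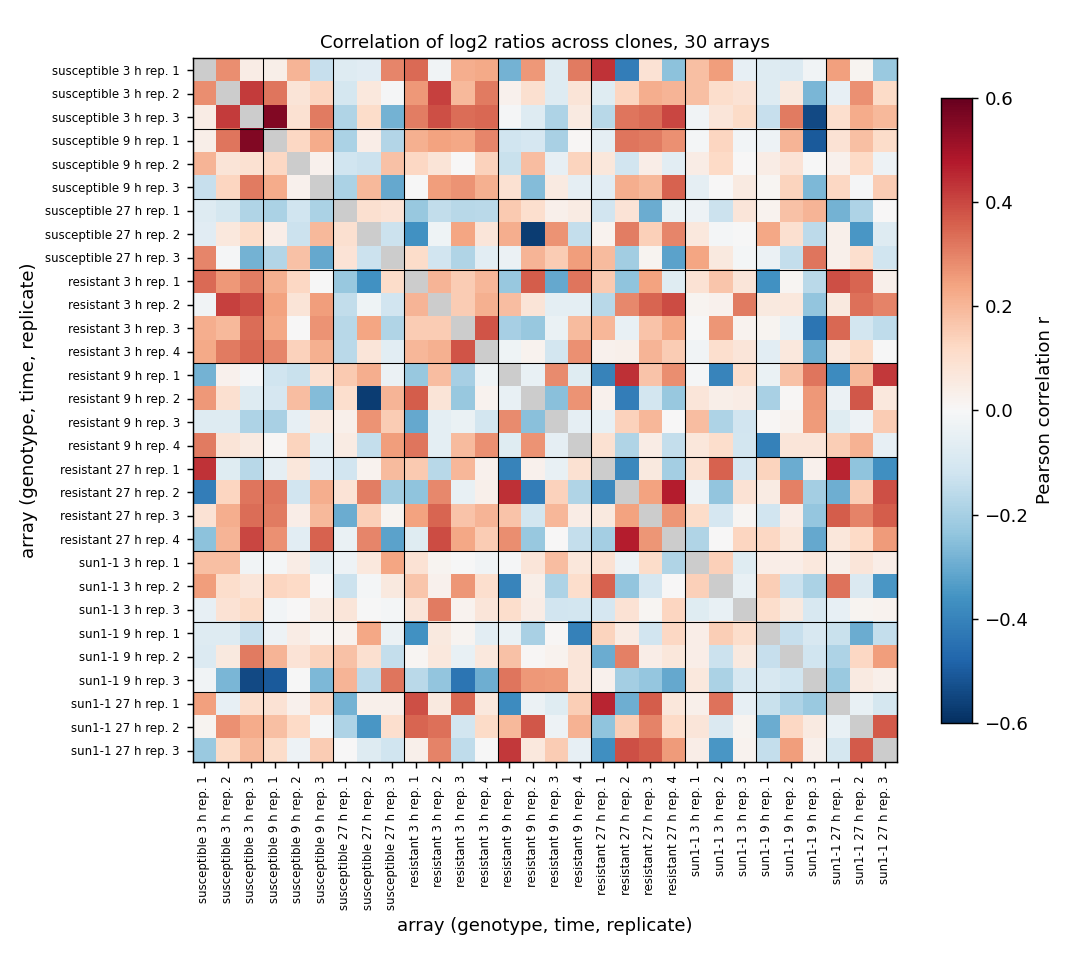
Heat map of Pearson correlations of log2 ratios across clones between the 30 arrays, ordered by genotype, time and replicate, with lines between the groups and red for positive and blue for negative values. Correlations lay between -0.571 and 0.554, and 14 of the 36 pairs within a group were negative.

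The ratios at 3 h addressed the earliest response to the virus in each genotype. Named values here and below belong to 1 clone unless an average is stated, and 33 of 72 moved by over 1.5 times when the clones of the symbol were averaged and 19 when a replicate was left out. The clone named for a symbol can differ from one comparison to the next, so such values are not always of the same clone. In susceptible leaves LOC102599567 had a mean log2 ratio of 1.83 (SD 0.42, n = 3), with a positive value on 3 of 3 arrays. LOC102595943 averaged -0.66 (SD 0.12, n = 3), and its 5 other clones were negative as well, between -0.68 and -0.49. RSI5 averaged 1.66 (SD 1.04, n = 3), or 1.06 without replicate 2. None of these clones passed the test: limma called 0 of 8219 clones in susceptible leaves, with 427 at an unadjusted p under 0.05 and a lowest adjusted p of 0.295. Other settings gave up to 116 calls, the most with array quality weights. When 402 genes were tested in place of the clones, LOC102599567 passed (adjusted p = 0.0294, against 0.00489 to 0.820 over its 13 settings) with its value unchanged at 1.83. It had no other clone to average, so the call went with the smaller number tested, and among 732 clones with a symbol 0 passed.

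In resistant leaves at 3 h LOC102595943 averaged -0.76 (SD 0.10, n = 4) and was negative on 4 of 4 arrays, with its 5 other clones between -0.76 and -0.52. GAPDH, the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, averaged -0.55 (SD 0.23, n = 4), and its 6 other clones were also negative, between -0.39 and -0.09 (all averaged -0.32). LOC102577562 averaged -0.61 (SD 0.30, n = 3). The limma test passed 0 of 6093 clones, 613 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0682. Scaling of the arrays gave 1 call and array quality weights gave 2.

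In sun1-1 leaves at 3 h SRE1A averaged 0.72 (SD 0.37, n = 3), with its 2 other clones at 0.65 and 0.91. DHAR, a dehydroascorbate reductase of the ascorbate cycle, averaged -1.01 (SD 1.24, n = 3), a value that shrank to -0.29 without replicate 3, the array of the widest spread, and to -0.029 with clones averaged. Since 0 other clones of DHAR could be tested, that average drew on spots with a value on fewer than 2 arrays of the group. A clone of LOC102580103 averaged 1.49 (SD 1.08, n = 2), while the 4 other clones of that symbol were negative, between -0.44 and -0.042. Of 7078 clones 0 passed by limma, 784 had an unadjusted p under 0.05, and the lowest adjusted p was 0.188. Without replicate 1, which left the array of the widest spread as 1 of 2, there were 273 calls.

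Averaged over the 3 genotypes at 3 h, a comparison added after the data were seen, LOC102595943 had the smallest p among genes. Over its 6 clones it averaged -0.60 (SE 0.116, 10 arrays) and was negative on 9 of 10 arrays, and it passed the test among 338 genes (adjusted p = 0.00770, against 0.00398 to 0.270 over the settings of its named clone). Its value at 3 h differed from its mean at 9 and 27 h by -0.58 (SE 0.143). It was picked for its value at 3 h, and over 305 genes that difference had a limma adjusted p of 0.115, so a constant dye effect stays open. LOC102596978 averaged 0.72 (SE 0.165) over 3 clones, was positive on 10 of 10 arrays and passed as well (adjusted p = 0.0303, against 0.0202 to 0.307). STWRKY8, a transcription factor of the WRKY family, which includes many regulators of plant defence, averaged 0.73 (SE 0.181) over 2 clones and was positive on 8 of 10 arrays. It missed the threshold among genes (adjusted p = 0.0507, against 0.00670 to 0.307). Its means were 0.89 (SD 0.30, n = 3) in susceptible, 0.75 (SD 0.80, n = 4) in resistant and 0.55 (SD 0.59, n = 3) in sun1-1 leaves, the resistant mean being 0.40 without replicate 4 and the sun1-1 mean 0.23 without replicate 3, the array of the widest spread. Among single clones limma called 4 of 5635, all without a symbol, with 960 at an unadjusted p under 0.05. The clones of spots 135409 and 142290 averaged -1.08 (SE 0.188, 9 arrays) and -1.17 (SE 0.193, 9 arrays), and those of spots 142904 and 160955 averaged 0.60 (SE 0.115, 10 arrays) and 0.59 (SE 0.110, 10 arrays). The count was 0 without replicate 2, 3 or 4, 36 without replicate 1, and 2 without sun1-1 3 h replicate 3. Among the 616 clones with a symbol, tested alone, 15 passed.

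At 9 h the clones with the smallest p in resistant leaves were those of LOC102598365, with 1.01 (SD 0.05, n = 2), LOC102594491, with 0.94 (SD 0.27, n = 2), and LOC102587499, with 0.96 (SD 0.88, n = 3). Of the 9 other clones of LOC102587499 only 4 were positive, over a range of -0.22 to 0.89, and its clones averaged 0.22. PR1B, a pathogenesis-related protein of the PR-1 family that marks salicylic acid responses, averaged 1.21 over 2 clones (SD 2.47, n = 3). By limma 0 of 5671 clones passed, 349 had an unadjusted p under 0.05, and the lowest adjusted p was 0.501. The count depended on replicate 3: without it 7 clones passed, all positive, among them 3 of LOC102587499 and the 2 of PR1B, at 2.35 and 2.62.

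In susceptible leaves at 9 h LOC102577512 averaged 0.52 (SD 0.61, n = 3; 0.27 over its clones and 0.16 without replicate 1), LOC102602779 averaged 0.60 (SD 0.11, n = 3) and 16R averaged -0.68 (SD 0.41, n = 2; -0.20 over its clones). By limma 0 of 7179 clones passed, with 349 at an unadjusted p under 0.05, and 0 passed with clones averaged by gene. In sun1-1 leaves LOC102577558 averaged 0.43 (SD 0.30, n = 3, with 2 of 4 other clones positive and 0.27 over its clones), LOC102604230 averaged 0.42 (SD 0.27, n = 3), and a clone of FLS, the enzyme flavonol synthase, averaged -0.57 (SD 0.44, n = 3). Only 1 of the 3 other clones of FLS was negative, over a range of -0.075 to 0.52, and its clones averaged -0.013 (the named clone was at -0.34 without replicate 1). Here 0 of 7898 clones passed by limma, and the 164 with an unadjusted p under 0.05 were fewer than the 394.9 that chance gives. The chance number is 0.05 of the clones tested, here and in every other comparison. The counts at 9 h in susceptible leaves (349 against 358.95) and in the mean of the 3 genotypes (166 against 270.55) also lay below it. PR1B averaged 0.79 (SD 0.29, n = 3) in sun1-1 and -0.09 (SD 0.66, n = 3) in susceptible leaves. Over the 3 genotypes LOC102577835 had the value 0.75 (SE 0.212), LOC102604230 had 0.29 (SE 0.0934) and LOC102589825 had 0.24 (SE 0.0675), or 0.13 over its clones. The other clone of LOC102577835, the one named at 27 h, was at 0.67 here. In that mean limma called 0 of 5411 clones, with 166 at an unadjusted p under 0.05, and no other setting gave a call in these 3 comparisons.

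At 27 h the ratios addressed the latest response, and the largest values of single named clones were in sun1-1 leaves. The 3 clones named next were each highest on replicate 1, which had the widest spread of the 3 arrays. A clone of LOC102577637 averaged 2.14 (SD 1.74, n = 2), from 3.37 on replicate 1 and 0.91 on replicate 3, with 2 other clones at 0.51 and 1.35 and 1.09 over its clones. A clone of LOC102587499 averaged 1.43 (SD 0.58, n = 3), and 6 of its 7 other clones were positive, over a range of -0.28 to 1.39 (0.64 over its clones, and 1.11 for the named clone without replicate 1). LOC102581985 averaged 1.03 (SD 0.52, n = 3), its 2 other clones averaged 0.94 and 1.05, and without replicate 1 it averaged 0.85. By limma 0 of 7697 clones passed, 712 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0634. With clones averaged, among 373 genes, LOC102581985 passed at 1.01 (SE 0.208, positive on 3 of 3 arrays, adjusted p = 0.0179, against 0.0112 to 0.936 over its settings), and 10 of 680 clones with a symbol passed when tested alone. Array quality weights gave 62 calls and clones with a value on all 30 arrays 3, and without replicate 3 a clone of LOC102587499 passed at 1.66.

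In resistant leaves at 27 h LOC102577835 averaged 1.13 (SD 0.56, n = 4), LOC102587499 averaged 0.78 (SD 0.39, n = 4) and LOC102601464 averaged 0.55 (SD 0.36, n = 4), each positive on 4 of 4 arrays. Another clone of LOC102587499 lay at -0.57, and its clones averaged 0.28. PR1B averaged 0.44 (SD 0.90, n = 4) and STWRKY8 -0.28 (SD 0.53, n = 4). By limma 0 of 6827 clones passed, 395 had an unadjusted p under 0.05, the lowest adjusted p was 0.843, and no other setting gave a call. In susceptible leaves LOC102597590 averaged 0.82 (SD 0.59, n = 2). PHA1, a proton pump of the plasma membrane, averaged -0.54 (SD 0.60, n = 3), was negative on 2 of 3 arrays, and moved to -0.23 without replicate 3 and -0.83 without replicate 1. A clone of LOC102577656 averaged -1.01 (SD 0.35, n = 2) while the other clone of that symbol was at 0.33. Here limma called 0 of 6832 clones, 539 had an unadjusted p under 0.05, and no other setting gave a call.

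Over the 3 genotypes at 27 h a clone of LOC102577835 averaged 1.09 (SE 0.203) and a clone of LOC102587499 averaged 0.84 (SE 0.153). Both were positive on 10 of 10 arrays and had an adjusted p of 0.0361. These were the 2 calls of limma among 5603 clones, with 474 at an unadjusted p under 0.05. With clones averaged, among 337 genes, LOC102577835 passed at 1.04 (adjusted p = 0.00626, against 0.00436 to 0.623 over its settings). LOC102587499, whose 7 other clones ran from -0.08 to 0.83, did not, at 0.38 (adjusted p = 0.107, against 0.00265 to 0.623). F3H, the flavonoid enzyme flavanone 3-hydroxylase, averaged 0.68 (SE 0.180) without passing the test. The count was 0 without replicate 2, where LOC102577835 fell to 0.72, 0 without replicate 4 and 0 without sun1-1 27 h replicate 2 or with that column as deposited. Without replicate 1 it was 1, a clone without a symbol, and among the 613 clones with a symbol it was 5.

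**Figure D2:**
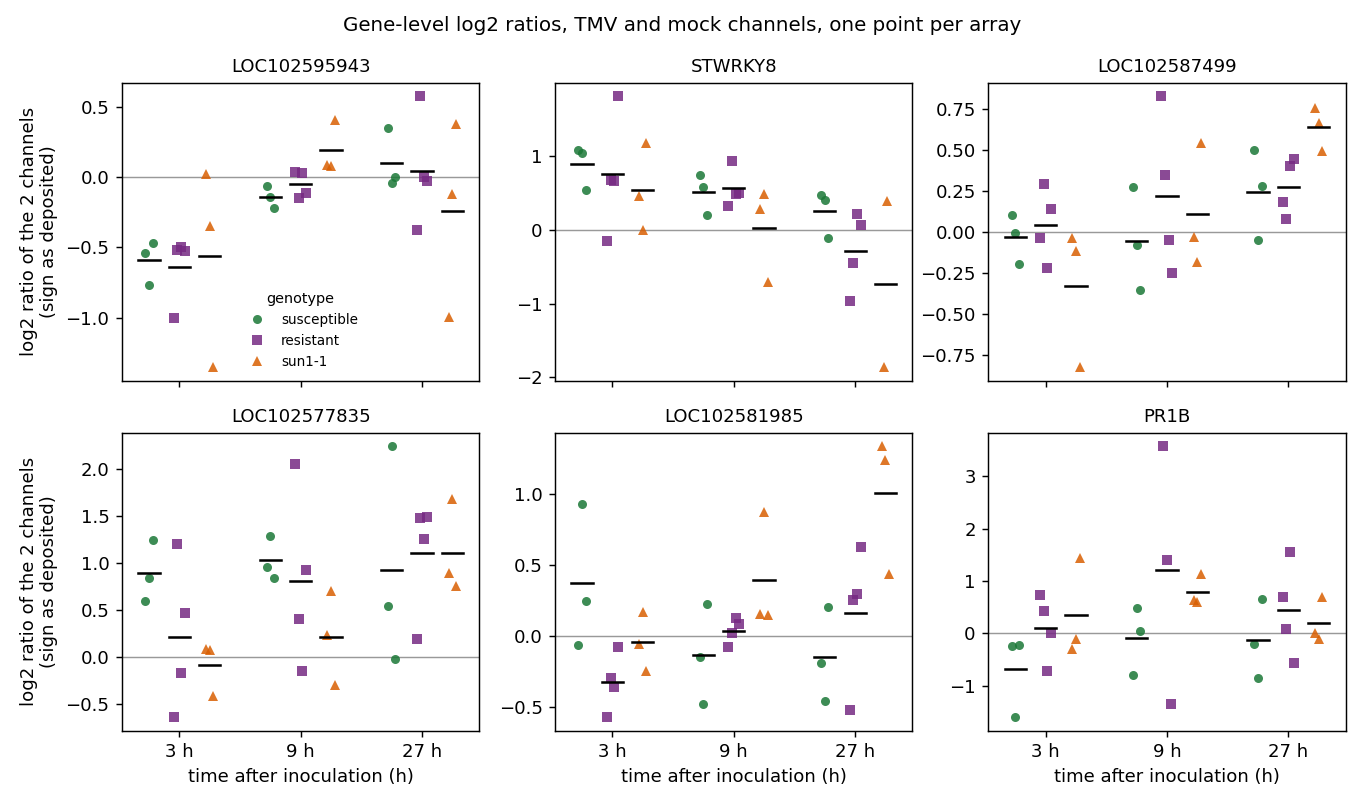
Log2 ratios of the TMV and mock channels for 6 genes, averaged over the clones of each symbol, against time after inoculation in h, with 1 point per array, a colour and marker for each genotype, a black bar for each group mean and signs as deposited. LOC102595943 was negative on 9 of 10 arrays at 3 h, and PR1B had an SD of 2.47 over the 3 arrays of resistant leaves at 9 h.

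The genotypes were compared at each time to ask whether N, or the sun1-1 mutation in plants with N, altered the response. Between resistant and susceptible leaves, LOC102599567 at 3 h averaged 0.32 (SD 0.34, n = 3) in resistant and 1.83 (SD 0.42, n = 3) in susceptible leaves, a difference of -1.51 (SE 0.447). LOC102581985 differed by -0.75 (SE 0.274), or -0.42 without replicate 2, and LOC102577562 by -0.49 (SE 0.217). At 9 h LOC102598365 averaged 1.01 (SD 0.05, n = 2) in resistant and -0.44 (SD 0.32, n = 3) in susceptible leaves, a difference of 1.44 (SE 0.320), LOC102594491 differed by 1.11 (SE 0.306) and LOC102577512 by -0.83 (SE 0.222), or -0.48 over its clones and -0.47 without replicate 1. At 27 h LOC102601763 averaged 0.30 (SD 0.14, n = 4) and -0.36 (SD 0.14, n = 3), a difference of 0.66 (SE 0.166), with the same sign within each group. LOC102577431 differed by 0.92 (SE 0.279) and LOC102577567 by 0.95 (SE 0.319), with all other clones of both symbols in the same direction. No clone passed: limma called 0 of 5949, 0 of 5476 and 0 of 5914 clones at 3, 9 and 27 h, with 91, 374 and 357 at an unadjusted p under 0.05, and no other setting gave a call.

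Between resistant and sun1-1 leaves, DHAR at 3 h averaged 0.28 (SD 0.21, n = 4) in resistant and -1.01 (SD 1.24, n = 3) in sun1-1 leaves, a difference of 1.29 (SE 0.367), or 0.57 without sun1-1 3 h replicate 3 and 0.25 with clones averaged. Here too 0 other clones of DHAR could be tested. DHAR2, another dehydroascorbate reductase, differed the other way, by -0.87 (SE 0.286), and LOC102577512 differed by 0.83 (SE 0.273), and without that array these were -0.49 and 0.38. At 9 h LOC102594491 differed by 1.21 (SE 0.306), LOC102587499 by 0.86 (SE 0.394) and LOC102577558 by -0.67 (SE 0.270). Only 4 of 8 other clones of LOC102587499 and 2 of 4 of LOC102577558 went the same way, and over their clones the differences were 0.11 and -0.28. Without replicate 1 they were 0.28 and -0.28, and without replicate 3 that of LOC102587499 was 1.70. At 27 h VPE2, a vacuolar processing enzyme, averaged 0.12 (SD 0.41, n = 4) in resistant and 2.45 (SD 1.82, n = 2, with 3.74 on replicate 1 and 1.17 on replicate 3) in sun1-1 leaves, a difference of -2.33 (SE 0.708), or -0.54 with clones averaged. No other clone of VPE2 had enough arrays to be tested in this comparison. LOC102577637 differed by -1.69 (SE 0.531), or -0.78 over its clones, and LOC102596783 by -1.21 (SE 0.368; -0.46 with array quality weights). By limma 0 of 5683, 0 of 5576 and 0 of 6344 clones passed at 3, 9 and 27 h, with 379, 93 and 334 at an unadjusted p under 0.05, and no other setting gave a call.

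Between sun1-1 and susceptible leaves at 27 h, LOC102581985 averaged 1.05 (SD 0.53, n = 3) in sun1-1 and -0.17 (SD 0.34, n = 3) in susceptible leaves, a difference of 1.22 (SE 0.307), with 1.12 and 1.13 for its 2 other clones. LOC102577637 differed by 2.35 (SE 0.560), or 1.29 over its clones. A clone of VPE2 differed by 2.95 (SE 0.747), while its other clone gave -0.05 and the average of its clones 0.90. Over the 2 sun1-1 arrays with a value the SD was 1.74 for the clone of LOC102577637 and 1.82 for that of VPE2, wider than these SEs reflect. At 3 h LOC102599567 averaged -0.13 (SD 0.28, n = 2) in sun1-1 and 1.83 (SD 0.42, n = 3) in susceptible leaves, a difference of -1.95, a clone of LOC102580103 differed by 1.39 (SE 0.400; 0.16 over its clones) and LOC102577512 by -0.92 (SE 0.330), the last being -0.33 without sun1-1 3 h replicate 3. At 9 h LOC102577512 differed by -0.81 (SE 0.237), LOC102586069 by -0.77 (SE 0.275) and a clone of FLS by -0.83 (SE 0.307). Over their clones these were -0.49, -0.51 and -0.013, without replicate 1 the first 2 were -0.40 and -0.36, and only 1 of 3 other clones of FLS went the same way. The limma counts were 0 of 6823, 0 of 6790 and 0 of 6126 clones at 3, 9 and 27 h, with 341, 296 and 752 at an unadjusted p under 0.05 and a lowest adjusted p of 0.108 at 27 h. At 27 h array quality weights gave 1 call and the omission of replicate 3 gave 1 call, both of clones without a symbol. No other setting gave a call at 3 or 9 h.

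The change over time asked how the response of each genotype developed. In sun1-1 leaves a clone of LOC102587499 averaged -0.68 (SD 0.67, n = 3) at 3 h and 1.43 (SD 0.58, n = 3) at 27 h, a difference of 2.11 (SE 0.392), and its 7 other clones differed in the same direction (0.96 over its clones). LOC102577637 differed by 2.65 (SE 0.560), with its 2 other clones at 0.85 and 1.67 (1.48 over its clones), and a clone of VPE2 by 2.87 (SE 0.747), with the other at -0.16 and 1.15 for the average of its clones. In resistant leaves LOC102595943 averaged -0.76 (SD 0.10, n = 4) at 3 h and 0.17 (SD 0.39, n = 4) at 27 h, a difference of 0.93 (SE 0.237), with its 5 other clones between 0.48 and 0.79. LOC102594491 differed by -0.54 (SE 0.256), and LOC102598365 by 0.19 (SE 0.268; 0.071 without replicate 2), its largest mean being that at 9 h. In susceptible leaves LOC102600559 averaged 0.38 (SD 0.13, n = 3) at 3 h and -0.37 (SD 0.41, n = 3) at 27 h, a difference of -0.75 (SE 0.220; -0.46 over its clones and -0.45 without replicate 1), LOC102577512 differed by -0.65 (SE 0.237) and LOC102577431 by -0.60 (SE 0.299), which moved to -0.13 without replicate 3 and -0.93 without replicate 2. By limma's F test 0 of 5939, 0 of 5004 and 0 of 6262 clones passed in susceptible, resistant and sun1-1 leaves, with 385, 299 and 484 at an unadjusted p under 0.05. For sun1-1 clones with a value on all 30 arrays gave 1 call, LOC102587499, clones with a symbol gave 1, also LOC102587499, and the omission of replicate 3 gave 1. No setting gave a call for the other genotypes.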

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

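Across the settings 322 of 373 counts equalled the reported ones, 5 changed within 1.5 times and 46 changed more, and of 1017 values of named clones 960 kept their direction and side of the threshold, 41 newly passed, 15 no longer passed and 1 reversed. The reported count was 0 in all 21 planned comparisons and in the mean at 9 h, so most equal counts were 0 against 0. Only 2 named values had passed, those of LOC102587499 and LOC102577835 in the mean at 27 h. The 15 that no longer passed were all theirs, out of 16 and 15 settings. The mean over genotypes, the omission of 2 single arrays, the displaced column, the averaging of clones and the restriction to clones with a symbol were chosen after the data were seen. The size of the values held less well, since 41 of the 72 named values moved by over 1.5 times in at least 1 setting, 33 of them with the clones of a gene averaged and 19 with a replicate left out. Centring the arrays changed no count. The reversed value was that of LOC102580103 in sun1-1 at 3 h, which went from 1.49 to -0.041 when its clones were averaged, since the 4 other clones were negative. Scaling the arrays to 1 spread gave 3 calls in susceptible 3 h, 1 each in resistant 3 h, sun1-1 3 h and sun1-1 27 h, and 71 and 7 in the means over genotypes at 3 and 27 h. Array quality weights gave 116 calls in susceptible 3 h, 2 in resistant 3 h, 3 in sun1-1 3 h, 62 in sun1-1 27 h, 1 for sun1-1 against susceptible at 27 h and 257 in the mean at 3 h. The weights ranged from 0.0682 for sun1-1 3 h replicate 3 to 2.64 for sun1-1 27 h replicate 2. Clones with a value on all 30 arrays (650 tested) gave 3 calls in sun1-1 27 h, 1 for the change over time in sun1-1, and 0 and 1 in the means at 3 and 27 h. Fitting only the arrays compared gave 1 call in susceptible 3 h and 0 in the means at 3 and 27 h. Clones with a single symbol, tested alone, gave 10 calls in sun1-1 27 h, 1 for the change over time in sun1-1, and 15 and 5 in the means at 3 and 27 h. Averaging the clones of a gene, which also left out clones without a symbol (402 genes against 8219 clones in susceptible 3 h), gave 1 call each in susceptible 3 h, sun1-1 27 h and the mean at 27 h, and 2 in the mean at 3 h. The call in susceptible 3 h, LOC102599567, had no other clone to average. With single replicates left out the counts ran from 0 to 7 in resistant 9 h (7 without replicate 3), 0 to 273 in sun1-1 3 h (273 without replicate 1), 0 to 1 in sun1-1 27 h, in sun1-1 against susceptible at 27 h and in the change over time of sun1-1 (1 without replicate 3 in each), 0 to 36 in the mean at 3 h (36 without replicate 1) and 0 to 3 in the mean at 27 h (3 without replicate 3). The mean at 27 h had 0 calls without the 2 arrays of conflicting time, without sun1-1 27 h replicate 2, and with that column as deposited, and 3 with array quality weights or the replicate number as a block. The mean at 3 h had 5 calls without sun1-1 27 h replicate 2 and 5 with that column as deposited. Without sun1-1 3 h replicate 3 there were 2 calls in sun1-1 27 h and 2 in the mean at 3 h. With the replicate number as a block there was 1 call in sun1-1 27 h and 7 in the mean at 3 h. No clear sign was seen that the numbers pair the samples: 30 of 111 pairs of arrays with the same number in different groups correlated above 0.1, and for 8 of 30 arrays the closest partner bore the same number. These were correlations of deviations from group means, without a chance number beside them. Before group means were taken off, pairs sharing a number had a mean r of 0.0270 and other pairs 0.0475 (two-sided permutation p = 0.326). Pairs sharing genotype and number had -0.0201 and other pairs 0.0469 (two-sided permutation p = 0.0572). Neither label went with a higher correlation, but a pairing is not excluded. Apart from LOC102580103, the cause of these changes was not tested. Signal over background was not used here, so the limit it sets is unknown.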

Other observations

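The regroupings of the planned comparisons were planned, while the mean over genotypes with its turned signs and the tests of 33 further genes, of pairs of groups and of the explanations were chosen after the values were seen. Some genes of well known function stood out when adjusted over those genes alone, which is not independent evidence. In sun1-1 leaves at 27 h F3H averaged 1.22 (SD 0.84, positive on 3 of 3 arrays), with a limma adjusted p of 0.0274 adjusted over the list alone and of 0.0821 over all genes, and without replicate 1, the array of the widest spread in that group, it averaged 0.76. SKT3, a potassium channel, averaged 0.87 (SD 0.86, positive on 2 of 2 arrays, at 1.48 on replicate 1 and 0.26 on replicate 3), with limma adjusted p values of 0.0320 and 0.0821. METK1, an S-adenosylmethionine synthetase, averaged 0.45 over 9 clones (SD 0.20) and CAT1, a catalase, 0.44 over 3 clones (SD 0.39), and neither passed over the list (limma adjusted p = 0.183 and 0.190). PDHE1-A, a subunit of pyruvate dehydrogenase, averaged -0.58 in sun1-1 leaves at 3 h (SD 0.33, negative on 3 of 3 arrays, limma adjusted p = 0.0294 over the list and 0.185 over all genes) and -0.29 in the mean over genotypes at 3 h (SE 0.0867, negative on 8 of 10 arrays, limma adjusted p = 0.0328 and 0.0832). At 3 h STWRKY8 had a limma adjusted p of 0.0117 over the list and 0.0507 over all genes in the mean over genotypes, and at 27 h F3H had 0.0248 and 0.107.

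The pair of groups most alike was susceptible and resistant leaves at 3 h, whose 12 pairs of arrays had a mean r of 0.277 (range -0.0214 to 0.411). This was the highest of the 36 pairs of groups (permutation p = 0.0147 for the highest), and 12 of the 36 had a mean below 0. The first principal component of 2720 clones held 18.1% of the variance. Each of the 9 groups had arrays on both sides of 0 on this component. In 32 sets of 4 values from resistant arrays, Dixon's test found 0 values standing apart, where chance gives about 1.6.

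The number of clones at an unadjusted p under 0.05 was compared with other splits of the same arrays. Between resistant and susceptible leaves 26 of 35 splits gave as many as the real 91 clones at 3 h (highest other 205), 3 of 35 as many as 374 at 9 h (highest other 402) and 14 of 35 as many as 357 at 27 h (highest other 859), so chance could not be excluded. Between resistant and sun1-1 leaves it could not be excluded either: 13 of 35 gave as many as 379 at 3 h (highest other 639), 31 of 35 as many as 93 at 9 h (highest other 505) and 18 of 35 as many as 334 at 27 h (highest other 1483). Between sun1-1 and susceptible leaves the 10 splits were too few for a share under 0.05, with real counts of 341, 296 and 752 and highest others of 495, 438 and 719 at 3, 9 and 27 h. For the change over time 6, 29 and 53 of 100 regroupings gave as many as the 385, 299 and 484 clones in susceptible, resistant and sun1-1 leaves (highest others 499, 725 and 1003), so chance could not be excluded. In the mean over genotypes the sign of each array was turned at random. At 3 h only the real pattern, 1 of 100, gave as many as 960 clones (highest other 802). At 9 h 52 of 100 gave as many as 166 (highest other 551) and at 27 h 38 of 100 as many as 474 (highest other 1097), so chance could not be excluded there. At 3 h chance became less likely but was not excluded, since 1 of 100 is the least that 100 patterns can give. That comparison was also chosen after the values were seen. A constant dye effect would also be broken up by turned signs, so the count does not set it apart from a response. Counted by clones at an adjusted p under 0.05, 2 of 100 patterns, the real one included, gave as many as the 4 calls at 3 h (highest other 4) and 3 of 100 as many as the 2 calls at 27 h (highest other 52). In some comparisons the highest other split gave several times the real count, such as 505 against 93 and 1483 against 334. In others it was close to it or below it, such as 402 against 374 and 719 against 752. Whether a structure among the arrays that the groups do not follow lay behind this was not tested.

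The 2 clones past the threshold in the mean over genotypes at 27 h were weighed first. A dye effect alike at all times cannot be told apart from a response. The value at 27 h exceeded that at 3 h by 1.06 (SE 0.217) for LOC102587499, or 0.49 (SE 0.143) over its clones. For LOC102577835 it did so by 0.70 (SE 0.299). The means at 3, 9 and 27 h were -0.22, 0.44 and 0.84 for LOC102587499, the first of the opposite sign. For LOC102577835 they were 0.39, 0.67 and 1.09. Both were picked for their size at 27 h, and over all 4396 clones these differences had a limma adjusted p of 0.182 and 0.513. This adjustment replaced a bound of 3 SE, here and at 3 h, after the values were seen. By that bound LOC102587499 had differed and LOC102577835 had not. The means at 27 h did not rest on the moved column alone, since without that array the lower of both lay 4.52 SE from 0. Both clones were picked for their size over arrays that included it, so a mean near 0 was unlikely from the start. The calls did depend on it. Both ended without that array (limma adjusted p = 0.0912 and 0.112), as the SE grew and the second value fell (LOC102587499 0.84, SE 0.153, before and 0.87, SE 0.169, after, and LOC102577835 1.09, SE 0.203, before and 0.99, SE 0.219, after). Both also ended with the column as deposited. Chance was not excluded for the count at an unadjusted p (38 of 100 patterns), while 3 of 100 gave as many calls, and a response shared by the genotypes stays open.

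The clones past the threshold in the mean over genotypes at 3 h were weighed next. A constant dye effect would leave them alike at all times. Spots 135409, 142290, 142904 and 160955 differed at 3 h from their mean at 9 and 27 h by -0.80 (SE 0.227), -0.93 (SE 0.232), 0.44 (SE 0.144) and 0.50 (SE 0.138), all over the replaced bound of 3 SE. That mean kept the sign of the 4 but was smaller, at -0.29, -0.23, 0.16 and 0.096. The 4 were picked for their size at 3 h, however. Once the differences of all 4396 clones were adjusted for, 0 of the 4 differed (lowest limma adjusted p of the 4 0.360), so a constant dye effect cannot be told apart from a response. The array of the widest spread, sun1-1 3 h replicate 3, held no value for 2 of the 4, those of spots 135409 and 142290. The values of the other 2 did not rest on that array alone, since without it the lower lay 4.32 SE from 0. Both had been picked for their size over arrays that included it, so a value near 0 was unlikely from the start. Both of these calls ended without it, as the value of spot 142904 fell (0.60, SE 0.115, before and 0.48, SE 0.110, after, limma adjusted p = 0.109) and the SE of spot 160955 grew (0.59, SE 0.110, before and 0.60, SE 0.121, after, limma adjusted p = 0.0697). An early response common to the 3 genotypes stays open, and a difference between the plants taken for TMV and mock at 3 h, and a dye effect particular to those arrays, were not tested.

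Arrays of 1 group that correlated below 0 were weighed last. Noise of single spots draws correlations towards 0, but 12 of 36 pairs within a group lay over 2 SE below 0. Channels exchanged on single arrays of 1 shared pattern leave no triple of arrays with a negative product of correlations, and 0 of 18 triples had one with all 3 correlations over 2 SD from 0 (SD 0.195, over pairs of arrays of different groups), a bound that replaced 0.1 in size and then 2 SE after the values were seen. No triple of either sign passed that bound, and the 4 with a negative product and all 3 correlations over 2 SE would have gone against an exchange at 2 SE but decide nothing, since that SE over clones holds no spread between plants, so exchanged channels cannot be told apart from other sources in any group. Differences between single plants, since each RNA sample came from 1 plant, could add to the pattern, and no biological explanation was tested beyond genotype and time.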
